A study of Mus musculus with 2 samples.

How the data were processed

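H3K27me3, the trimethylation of lysine 27 on histone H3 that Polycomb repressive complexes place on silent genes, was profiled by chromatin immunoprecipitation and sequencing in mouse intestine at embryonic day 16.5. Per the labels, the tissue came from embryos of both sexes of the B6NCrl strain, pooled before fixation, and the DNA was in a size range of 300 to 500 bp. There was 1 group with 2 biological replicates, each made of 2 technical replicates that had been combined, and the label of replicate 2 gives 41 embryos. Each replicate is thus a pool of animals, and the spread between the replicates is a spread between pools.

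The values start from 4 deposited peak lists on the mm10 build, in the narrowPeak layout: 1 called on each replicate, 1 called on both replicates together, and 1 named replicated. Each peak carries an enrichment value that is a signal or coverage measure from the authors' peak caller, whose scale is not stated, and it was used only to rank or describe peaks within 1 list. Each peak also carries a −log10 q value from the authors, deposited in the same lists, which was used for a stricter selection. Per the deposited descriptions, the list of replicate 1 was derived from its alignments and 2 further files, and that of replicate 2 from its alignments and 1 further file. What these further files hold, the aligner, the peak caller and the rule by which a peak entered the replicated list are not given in the sources used here. If the controls differed between the replicates, peak numbers could differ for that reason alone. The lists hold no read counts, so the sequencing depth is unknown, no counting interval can be given, and the presence of a peak is a call that depends on a depth and a background that cannot be read from the lists. A gene without a listed peak is therefore a gene without a call, not a gene shown to lack the mark.

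Each row of the replicated list was also a row of the pooled list. The main results use the replicated list, and the promoter, CpG, X chromosome, gene list and Hox results were also computed from each replicate's own list. The bases per part of the genome, the numbers of wide regions, the tests of gene families and the comparison of gut lineage genes with neural factors are given for the replicated list. Peaks counted as overlapping when they shared at least 1 base. Chance overlap was measured with 1000 seeded circular shifts of the peaks within each chromosome, which keep peak numbers, widths and clustering. The test is one-sided, and 0.001 is the smallest p that the 1000 shifts can give. Analyses covered the 19 autosomes and the X chromosome.

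Genes were the 21755 protein-coding genes of GENCODE release M21 on these chromosomes, whose build was the same as that of the peaks. A promoter was the 1 kb on both sides of any annotated transcription start. A promoter was called CpG-rich when the 1 kb on both sides of the 5'-most start had a CpG observed-to-expected ratio of at least 0.6 and a GC fraction of at least 0.5, which held for 6548 genes, and 15207 genes were called CpG-poor. For each gene, the share of the 10 kb window centred on the 5'-most start that was covered by peaks was computed in each replicate and is given as the mean ± SD with n = 2. The wide regions were made by joining peaks of the replicated list across gaps of at most 3 kb.

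Before the data were examined, 20 gene lists were fixed for the tissue, its cell types, other organs and known classes of Polycomb targets, together with the tests and the rule for genes to be named. The rule took, per list, every member with a promoter peak where at most 5 had one and otherwise the 4 with the highest mean coverage, plus the first 3 in list order without a peak. It also took genes with a promoter in the 10 widest regions and the 5 genes per replicate with the strongest promoter peak found in that replicate alone, and it allowed every Hox gene to be named. Lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Genes, not animals, are the units of these tests, and neighbouring genes can share a peak. Some lists also share members and are not separate evidence. Among these, Pax6, Nkx2-2 and Lmx1a are on the neural and the secretory lists. Isl1 is on the mesoderm and secretory lists, and Mnx1 on the endoderm organ and secretory lists. Sox17 and Prox1 are on the endoderm organ and endothelial lists. Differences between sets of genes in coverage or enrichment value were tested by permuting genes 100000 times.

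The alternatives were the pooled list, each replicate's own list, peaks with a −log10 q of at least 2, a promoter of 2.5 kb on both sides, the 5'-most start alone, at least 500 bases of peak in the promoter, CpG-rich promoters alone, list members within 200 kb counted once, gaps of 1 kb and 10 kb, equal numbers of peaks, and a stricter overlap. The scripts were tested on simulated data. Of 10000 simulated peaks with a planted overlap of 60%, 60.1% were found overlapping. For promoters the expected share was 33.3%, and 33.2% was found. That expected share was the planted one plus a part taken from the shifts of the same run, so the check is partly built in. Of simulated lists with 25 genes of which 15 carried a peak, 100% passed the threshold, and 5% of unrelated lists had an unadjusted p under 0.05. The planted lists all had the same counts, so their result is the same calculation repeated. The simulated marks were drawn independently for each gene, so this check does not cover neighbouring genes that share a peak. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1.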

Results

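H3K27me3 was mapped in mouse intestine at embryonic day 16.5, a stage at which the gut wall holds epithelium, mesenchyme with smooth muscle, enteric neurons and glia, vessels and blood cells. The design has 1 group of 2 biological replicates and no second tissue, stage or condition. The comparisons it allows are between the replicates, between peaks and the rest of the genome, and between groups of genes. The question was where the mark lies and which genes carry it. The peak lists hold no read counts, so the depth of each replicate is unknown.

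Called H3K27me3 peaks covered a small part of the genome, and the replicates differed in how much of it was called. The covered length is the extent of these mostly narrow calls and not a measure of the extent of the mark. Replicate 1 had 51397 peaks over 21.7 Mb, or 0.849% of the sequenced bases, and replicate 2 had 27651 peaks over 9.05 Mb, or 0.354%. The mean was 15.4 Mb ± 8.96 (SD, n = 2), and the covered length differed 2.40-fold between the replicates. The median peak width was 257 bp in replicate 1 and 231 bp in replicate 2. A −log10 q of at least 2 was reached by 58.7% of the peaks of replicate 1 and by 28.1% of those of replicate 2. The authors' replicated list held 18905 peaks over 14.3 Mb, with a median width of 456 bp. Of these, 11644 overlapped a peak in the own list of both replicates and 7261 did not, and the 11644 carried 80.8% of the covered bases.

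Peaks with a high enrichment value were mostly shared and the weak peaks of replicate 1 mostly were not. Of the peaks of replicate 1, 25.1% were overlapped by a peak of replicate 2, against 0.715% after shifting. Of the peaks of replicate 2, 65.8% were overlapped by a peak of replicate 1, against 1.44% after shifting. The Jaccard index of covered bases was 26.2% against 0.263% after shifting. The permutation p was 0.001 for each of these values, the smallest that the shifts can give. In the top decile of peaks by enrichment value, 85.5% of the peaks of replicate 1 and 98.1% of the peaks of replicate 2 were shared. In the lowest decile the shares were 9.16% and 58.0%. With both lists held to a −log10 q of at least 2, 17.1% of the peaks of replicate 1 and 89.1% of those of replicate 2 were shared. With at least 50% of a peak's length required, 7417 peaks of replicate 1, or 14.4%, and 16589 of 27651 peaks of replicate 2 were shared. With equal numbers of peaks the shares were 37.6% and 57.6%.

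**Figure D1:**
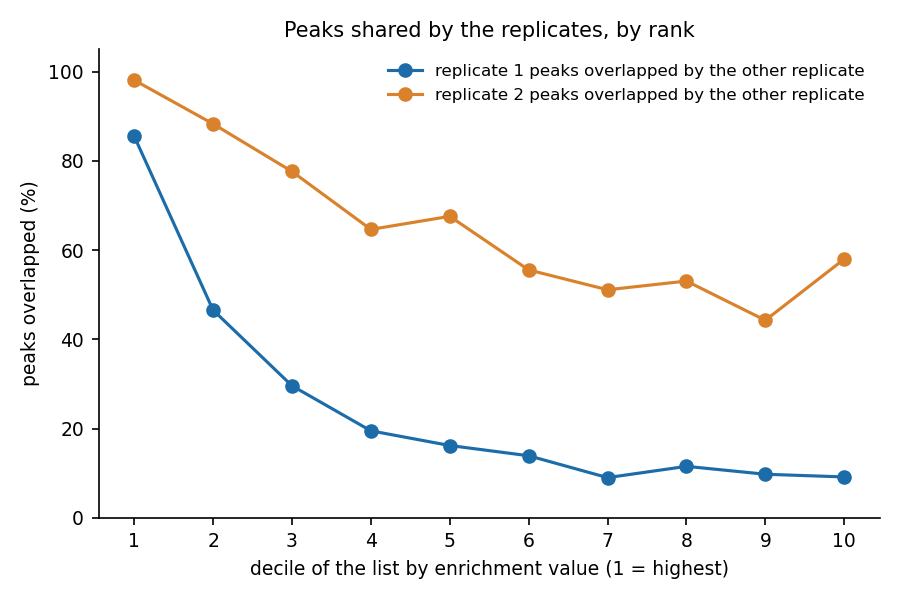
Percent of each replicate's peaks overlapped by at least 1 base by a peak of the other replicate (vertical axis), per decile of its list ranked by the authors' enrichment value (horizontal axis, 1 is the highest decile). The share is 85.5% in the top decile of replicate 1 and 9.16% in its lowest decile, and 98.1% and 58.0% in replicate 2.

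Promoters of protein-coding genes were the most enriched part of the genome that was examined. They made up 3.81% of the sequenced bases and 31.1% of the bases in the replicated list, a density 8.17-fold that of the genome. Exons outside promoters held 8.06% of the covered bases, sequence outside protein-coding genes and promoters 35.8%, and introns the rest. Of the peaks in the replicated list, 31.5% touched a promoter against 5.08% after shifting, which is 6.20-fold (permutation p = 0.001, the smallest that the shifts can give). The same ratio was 4.31 in replicate 1 and 6.08 in replicate 2. A promoter peak was found at 3118 of 21755 genes, or 14.3%. The replicates' own lists marked 4388 and 3019 genes, a mean of 17.0% ± 4.45 (SD, n = 2) of all genes. Both replicates marked 2791 genes, against 609 for independent lists of these sizes. Promoters rich in CpG, the class at which Polycomb complexes are known to gather in mammals, carried a peak more often than others. The shares were 18.4% of 6548 CpG-rich and 12.6% of 15207 CpG-poor promoters (odds ratio 1.56, Fisher's exact p = 1.23e-27). The odds ratio was 1.28 in replicate 1 and 1.53 in replicate 2. The CpG criterion was an average over the 1 kb on both sides of the 5'-most start. A promoter with a shorter CpG-rich stretch, or with one at another start, can thus count as CpG-poor. Gapdh, Six3, Neurog3 and Wnt1 were in that class. The odds ratio therefore does not compare promoters with and without CpG islands.

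Nearly all of the listed transcription factors that build other organs carried the mark. All 49 neural transcription factors on the fixed list had a promoter peak in the replicated list and in the own list of both replicates, against 14.1% of other genes (adjusted Fisher's exact p = 3.30e-41). The most covered were Lhx5, Six3, Olig2 and Neurog1, regulators of forebrain, spinal cord and sensory neurons. Peaks covered 88.7% ± 8.24 of the 10 kb around the start of Lhx5, 88.4% ± 9.32 at Six3, 87.2% ± 12.1 at Olig2 and 85.9% ± 18.0 at Neurog1 (SD, n = 2 for each). Of 34 factors of muscle, heart, limb and other mesoderm, 30 had a promoter peak (adjusted Fisher's exact p = 7.42e-21). Coverage was 79.6% ± 11.7 at Uncx, which acts in the somites, 77.7% ± 16.3 at T, the mesoderm gene brachyury, 77.2% ± 15.9 at Wt1, a kidney and gonad regulator, and 76.4% ± 19.0 at Six2, a kidney progenitor factor (SD, n = 2). Among the 4 members without a promoter peak were Myf5, Myf6 and Myog, regulators of skeletal muscle, whose 10 kb windows held no peak in either replicate. Of 22 factors of foregut, pancreas and other endoderm organs, 21 had a promoter peak (adjusted Fisher's exact p = 1.38e-16). Coverage was 84.7% ± 17.6 at Irx1, 82.6% ± 16.6 at Foxe1, a thyroid regulator, 77.4% ± 11.5 at Irx2 and 76.5% ± 17.5 at Pax9, a regulator of thymus and tooth (SD, n = 2). The exception was Gcm2, the parathyroid regulator. Per replicate, the share of marked genes was 100% in both for the neural list, 88.2% ± 4.16 for the mesoderm list and 93.2% ± 3.21 for the endoderm list (SD, n = 2).

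**Figure D2:**
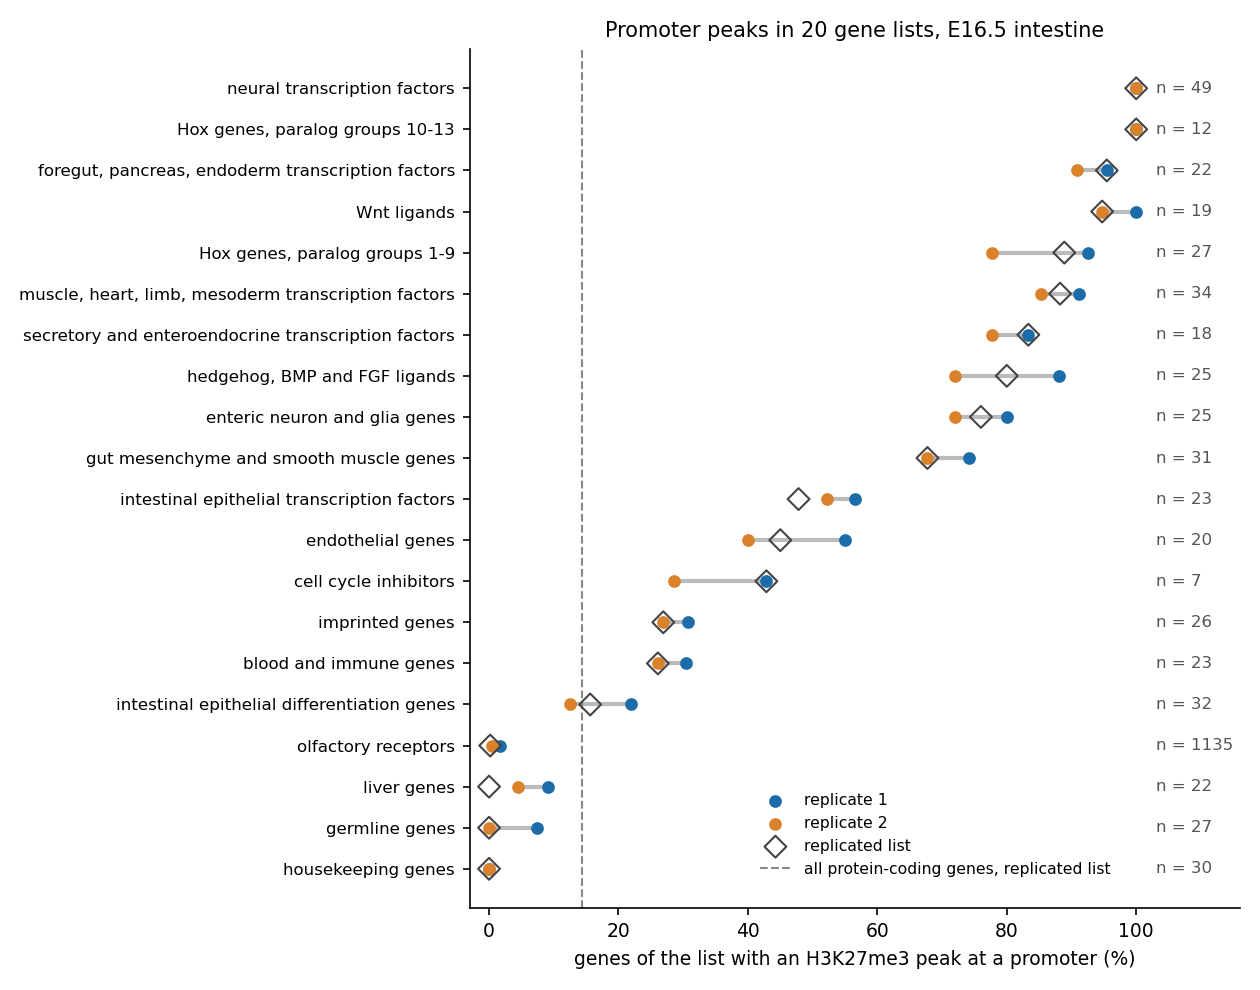
Percent of the genes in each of the 20 fixed lists with a peak at a promoter (horizontal axis), in replicate 1, replicate 2 and the replicated list, with the number of genes as n and the share of all protein-coding genes, 14.3%, as a dashed line. Lists of transcription factors and signalling ligands lie far above that line, and housekeeping genes, germline genes and olfactory receptors lie below it.

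Among genes of the gut epithelium, the listed transcription factors were marked more often than other genes and the differentiation genes were not. Of 23 transcription factors of the intestinal epithelium, 11 had a promoter peak, or 47.8% against 14.3% of other genes (adjusted Fisher's exact p = 2.18e-04). Foxa2 was covered by 61.3% ± 12.1, Cdx2, which sets intestinal identity, by 57.6% ± 32.9, Foxa1 by 41.1% ± 19.9 and Gata4 by 22.3% ± 16.6 (SD, n = 2). At Cdx2 the coverage was 80.9% in replicate 1 and 34.3% in replicate 2. Hnf4a, Hnf4g and Hnf1a, activators of enterocyte genes, had no peak in their 10 kb windows in either replicate. Secretory and enteroendocrine factors were marked in 15 of 18 cases (adjusted Fisher's exact p = 2.07e-10). Neurog3, which starts the enteroendocrine lineage, was covered by 78.7% ± 16.3, Insm1 by 69.1% ± 24.0, Nkx2-2 by 66.5% ± 16.9 and Fev by 65.4% ± 11.7 (SD, n = 2). The 3 members without a promoter peak were Spdef, Bhlha15 and Sox4. Among the marked members, Pax6, Nkx2-2, Lmx1a, Isl1 and Mnx1 are also on the lists for other organs. Intestinal epithelial differentiation genes, by contrast, carried a peak about as often as other genes, in 5 of 32 cases or 15.6% (adjusted Fisher's exact p = 0.8). Those 5 were Cdh1, Slc5a1, Epcam, Krt8 and Krt19, at coverages from 16.9% ± 15.4 at Cdh1 to 2.37% ± 0.240 at Krt19 (SD, n = 2), and the promoters of Epcam and Krt8 had a peak in replicate 1 and none in replicate 2. Vil1, Krt18 and Krt20 had none in either. In replicate 2 alone the share of the list was 12.5% against 13.9% of other genes, so its direction is not settled. The difference between the list of regulators and that of differentiation genes was not itself tested. The lists also differ in CpG class. CpG-rich promoters belonged to 11 of 23 epithelial factors and 10 of 18 secretory factors, but to only 2 of 32 differentiation genes. The kind of gene is therefore not separated from CpG class in this contrast.

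In the other cell types of the gut wall, the most covered gene of each list encoded a transcription factor, and several genes of differentiated functions had no promoter peak. Of 31 genes of gut mesenchyme and smooth muscle, 21 had a promoter peak (adjusted Fisher's exact p = 4.14e-11). The most covered were the mesenchymal factors Foxl1 at 66.4% ± 16.2, Foxf1 at 65.9% ± 27.9, Foxf2 at 63.8% ± 28.9 and Nkx3-2 at 54.5% ± 12.3 (SD, n = 2). Acta2, Actg2 and Tagln, which encode contractile proteins of smooth muscle, had no peak in the replicated list, although Tagln had a promoter peak in replicate 2. Of 25 genes of enteric neurons and glia, 19 had a promoter peak (adjusted Fisher's exact p = 1.65e-11). Tlx2 was covered by 75.3% ± 15.2, Hmx2 by 73.6% ± 30.7, Hmx3 by 70.0% ± 29.2 and Ascl1 by 68.4% ± 19.5 (SD, n = 2), while Elavl4, Vip and Plp1 had no peak in their windows. Other members that do not encode transcription factors, among them Tubb3, Chat and Nos1, had a promoter peak in the replicated list. Of 20 endothelial genes, 9 had a promoter peak (adjusted Fisher's exact p = 0.00145), among them the factors Sox18, Sox7 and Sox17 and the VEGF receptor gene Flt1. Coverage was 50.8% ± 29.8 at Flt1 and 45.7% ± 25.1 at Sox17 (SD, n = 2). Pecam1, Cdh5 and Tek had no promoter peak in the replicated list, and Cdh5 had one in replicate 1. Of 23 blood and immune genes, 6 had a promoter peak, which did not differ from other genes by the test (adjusted Fisher's exact p = 0.135). The most covered were Tal1 at 56.8% ± 36.6, Ikzf1 at 36.5% ± 12.3 and Lyl1 at 33.5% ± 14.4 (SD, n = 2), all transcription factors of blood cells. Cd14, which encodes a surface receptor, came next at 9.5% ± 10.7 (SD, n = 2) and had a promoter peak in both replicates. Ptprc, Cd3e and Cd4 had no promoter peak in the replicated list, and Cd3e had one in replicate 1.

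Genes of signalling ligands were marked far more often than other genes. Of 19 Wnt ligands, 18 had a promoter peak (adjusted Fisher's exact p = 3.42e-14). The exception was Wnt8a, which had one in replicate 1 and in the pooled list. Coverage was 79.2% ± 13.1 at Wnt10a, 75.1% ± 12.5 at Wnt3a and 63.5% ± 18.4 at Wnt1 (SD, n = 2). Of 25 hedgehog, BMP and FGF ligands, 20 had a promoter peak (adjusted Fisher's exact p = 9.30e-13), with 79.9% ± 13.1 covered at Gdf7, 51.3% ± 21.4 at Fgf3 and 50.6% ± 6.38 at Dhh (SD, n = 2). Bmp2, Bmp5 and Inhba were among those without, although Inhba had a promoter peak in replicate 1. Of 7 cell cycle inhibitors, Cdkn2a, Cdkn2b and Cdkn2c had a promoter peak (adjusted Fisher's exact p = 0.0773). Coverage was 49.3% ± 26.5 at Cdkn2a and 41.1% ± 14.6 at Cdkn2b (SD, n = 2), whereas the promoter of Cdkn2c had no peak in the own list of either replicate. Cdkn1a, Cdkn1b and Cdkn1c had none in the replicated list, and Cdkn1a had one in replicate 1.

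Genes used by every cell, genes of the germline and olfactory receptors were largely free of called peaks. None of 30 housekeeping genes, such as Actb, Gapdh and Hprt, had a promoter peak in any of the lists (adjusted Fisher's exact p = 0.0237 in the replicated list). None of 27 germline genes, such as Dazl and Sycp1, had one in the replicated list (adjusted Fisher's exact p = 0.0341), while Ddx4 was among 2 that had one in replicate 1, and the list missed the threshold there with an adjusted Fisher's exact p of 0.189. Both calls are lost when 500 bases of peak are asked for in the promoter, with adjusted Fisher's exact p of 0.0891 and 0.0886. Olfactory receptors, which lie in large gene clusters with few CpGs, had a promoter peak in 2 of 1135 cases, Olfr94 and Olfr222 (adjusted Fisher's exact p = 2.02e-73). Per replicate the share was 1.06% ± 0.872 (SD, n = 2). None of 22 liver genes had a promoter peak in the replicated list, Alb, Afp and Ttr included, which did not pass the threshold (adjusted Fisher's exact p = 0.0773). The own lists of replicates 1 and 2 marked 9.09% and 4.55% of the liver genes. Of 26 imprinted genes, 7 had a promoter peak (adjusted Fisher's exact p = 0.0956), with 77.8% ± 15.3 covered at Dio3, 33.4% ± 22.6 at Grb10, 27.8% ± 16.1 at Gnas and 27.4% ± 8.42 at Igf2 (SD, n = 2). Cdkn1c, Slc22a18 and Ddc had none in the replicated list.

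Hox genes, which set position along the body axis, were marked across all 4 clusters, and the posterior groups were covered more than the anterior ones. A promoter peak was found at 24 of 27 genes of paralog groups 1 to 9 (adjusted Fisher's exact p = 4.92e-17) and at all 12 genes of groups 10 to 13 (adjusted Fisher's exact p = 1.48e-10). The exceptions were Hoxa4, Hoxb2 and Hoxb4, of which Hoxb2 had a promoter peak in replicate 1. Nearly all promoters were marked in both sets, which leaves little room for a difference in that measure (Fisher's exact p = 0.539, two-sided). With 500 bases of peak asked for in the promoter, the shares lay 25.9 percentage points apart (Fisher's exact p = 0.0775). The covered share of the 10 kb windows differed. It averaged 40.7% ± 19.3 in groups 1 to 9 and 71.4% ± 20.5 in groups 10 to 13 (SD, n = 2). The difference was 31.6 percentage points in replicate 1 and 29.8 in replicate 2 (permutation p across genes = 0.00046, two-sided). Hox genes are neighbours and are not independent, but the posterior set was the more covered in each cluster and each replicate. In Hoxb the posterior set is Hoxb13 alone. Over whole clusters, coverage was 67.2% ± 25.2 at Hoxc, 57.3% ± 24.7 at Hoxd, 37.3% ± 16.3 at Hoxa and 28.6% ± 13.7 at Hoxb (SD, n = 2), and the clusters had this order in both replicates. Within Hoxa and Hoxb, several windows at anterior genes had low coverage, with 14.6% ± 15.1 at Hoxa2, 3.23% ± 4.56 at Hoxa4, 1.12% ± 1.58 at Hoxb4 and 8.07% ± 11.4 at Hoxb1, against 76.5% ± 17.8 at Hoxa9 and 77.5% ± 22.5 at Hoxb9 (SD, n = 2). Hoxa3, whose 5'-most annotated start lies between those of Hoxa6 and Hoxa7, was covered by 51.4% ± 31.1 (SD, n = 2). The 5'-most start of Hoxc5 likewise lies next to that of Hoxc10, and those of Hoxd3 and Hoxd4 nearly coincide. Some windows are therefore shared within a set or between the anterior and posterior sets, which the permutation across genes does not take into account.

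**Figure D3:**
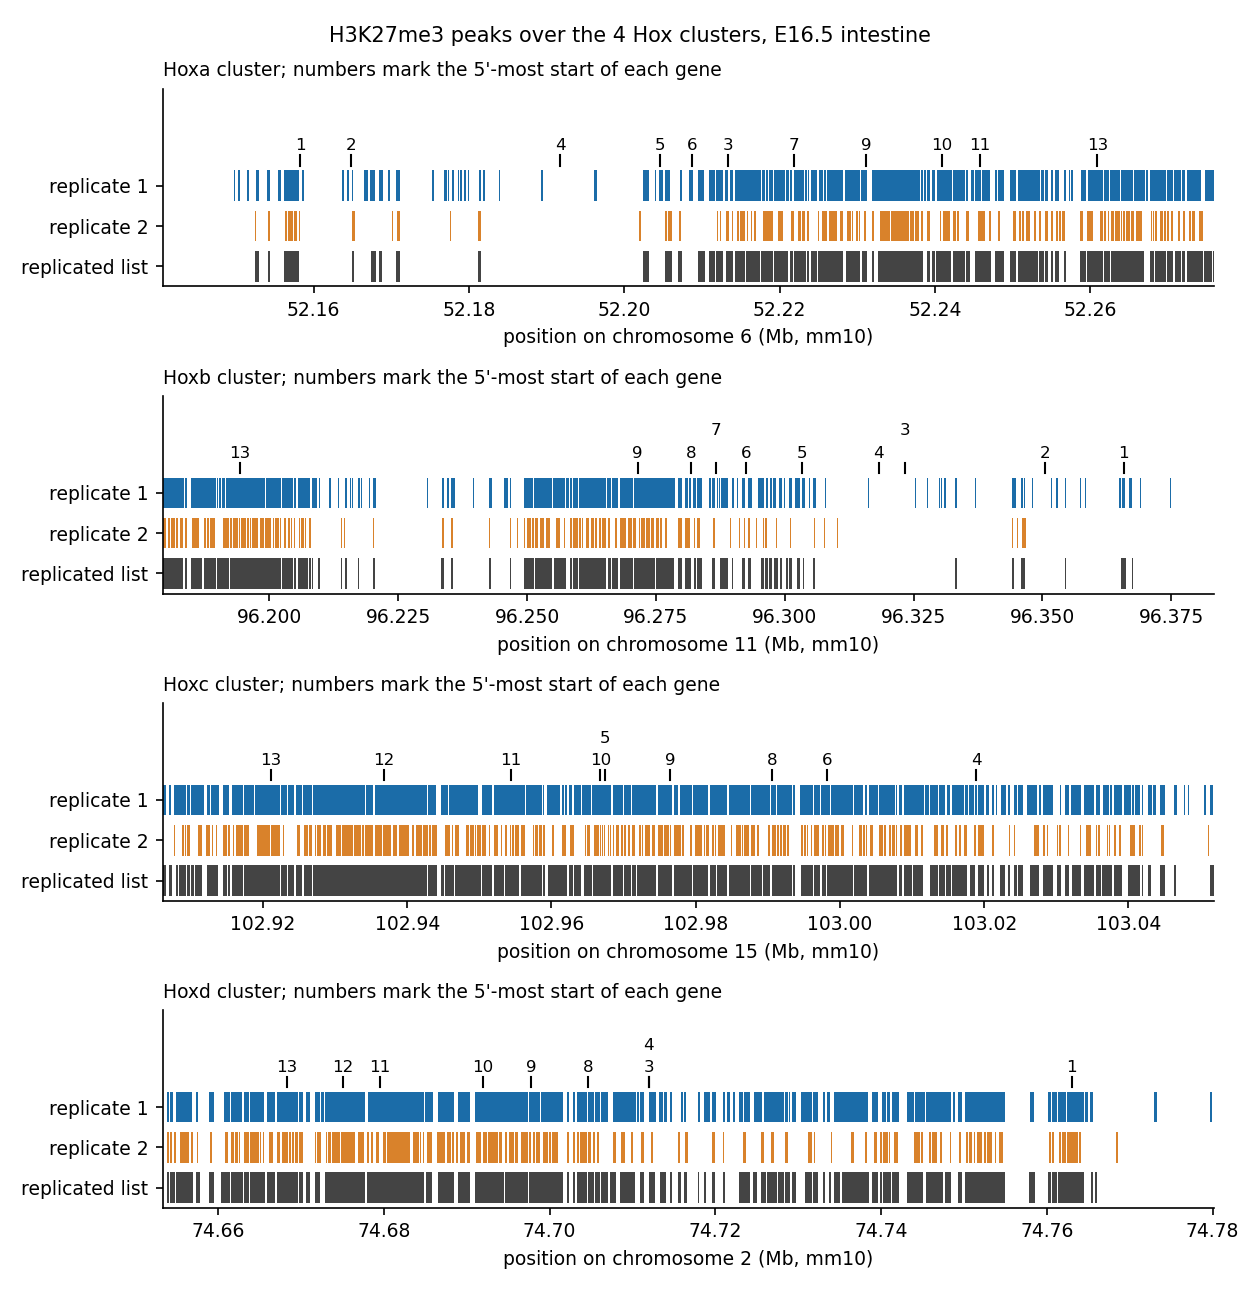
Stretches covered by peaks of replicate 1, replicate 2 and the replicated list over the Hoxa, Hoxb, Hoxc and Hoxd clusters, with mm10 positions in Mb on the horizontal axes and the 5'-most start of each gene marked by its number. Peaks run through the whole of the Hoxc cluster, with 67.2% covered as the mean of the replicates, and are sparse from Hoxb4 to Hoxb1 and around Hoxa4.

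The widest marked regions belonged to developmental regulators. Joining peaks across gaps of at most 3 kb gave 6824 regions with a median width of 1103 bp. Of these, 425 spanned at least 10 kb and held 40.8% of the covered bases. The widest, 148 kb on chromosome 15 from 102898631 to 103046610, held all 9 Hoxc genes and the long non-coding gene Hotair, and 63.4% ± 24.4 of it was covered (SD, n = 2). The next lay on chromosome 2 from 74644140 to 74766014 and held Evx2 and all 9 Hoxd genes. Parts of the Hoxa cluster, on chromosome 6 from 52202451 to 52277874, and of the Hoxb cluster, on chromosome 11 from 96246644 to 96305955, were also among the 10 widest. The others surrounded Zic1 and Zic4 on chromosome 9, Tbx5 on chromosome 5, Pax3 on chromosome 1, Pax2 on chromosome 19 and Dmbx1 on chromosome 4, all genes of transcription factors of neural tube, heart, limb or kidney. The remaining region, 73.0 kb on chromosome 7 from 79494147 to 79567192, held no protein-coding promoter but several long non-coding genes, among them Mir9-3hg, the host gene of a neural microRNA, and 76.3% of it was covered in replicate 1 and 46.6% in replicate 2. The median width of the 10 widest was 66.4 kb, and 74.4 kb and 54.1 kb in the own lists of replicates 1 and 2, a value that depends on the gap that is joined.

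The X was the only chromosome with more peaks in replicate 2 than in replicate 1. Relative to the autosomes, the covered share of the X was 0.701 in replicate 1 and 1.61 in replicate 2, and it was 0.710 in the replicated list, where 4 of the 19 autosomes were covered less than the X. Replicate 2 had fewer peaks than replicate 1 on the autosomes, 23737 against 47782, but more on the X, 3914 against 3615. Peaks per megabase on the X were 21.1 in replicate 1 and 22.9 in replicate 2, against 19.4 and 9.64 on the autosomes, which is 1.09-fold and 2.37-fold. In replicate 1 the X lay within the range of single autosomes, 10 of which had fewer peaks per megabase, and in replicate 2 all 19 had fewer. Of the X peaks of replicate 2, 22.5% were overlapped by replicate 1, against 73.0% of its autosomal peaks, and 10.1% of them reached a −log10 q of 2, against 31.0% on the autosomes. Promoters on the X were marked at 14.1% of genes in the replicated list, against 14.3% on autosomes. The shares were 20.5% against 20.2% in replicate 1 and 21.3% against 13.5% in replicate 2. For the covered share, the replicates lay on opposite sides of 1, and no direction can be given.

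**Figure D4:**
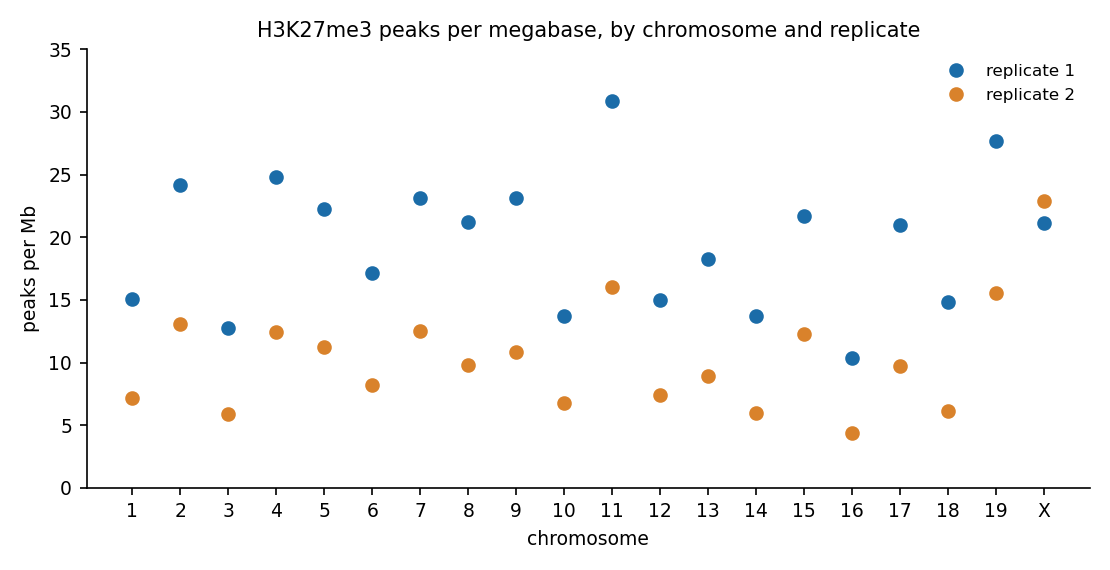
Peaks per Mb (vertical axis) on each autosome and the X chromosome (horizontal axis) in replicate 1 and replicate 2. Replicate 1 lies above replicate 2 on each of the 19 autosomes, and on the X replicate 2 lies above replicate 1, at 22.9 against 21.1 peaks per Mb.

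Promoter calls found in 1 replicate alone were mostly those of the longer list. A promoter peak was present in replicate 1 alone at 1597 genes and in replicate 2 alone at 228 genes, so 92.4% of the genes of replicate 2 were also marked in replicate 1. Genes on the X made up 32.9% of those found in replicate 2 alone and 4.20% of those found in replicate 1 alone. The strongest promoter peaks of replicate 1 at genes without a promoter peak in replicate 2 were at Plin5, Mafb, Fcgr3, Pax4 and Entpd3. Around Mafb, a factor of macrophages and hindbrain, 67.9% of the 10 kb window was covered in replicate 1 and 36.7% in replicate 2, so peaks lay near the promoter in both. In replicate 2 the windows of Plin5, Pax4, Fcgr3 and Entpd3 also held peaks, at coverages of 25.7%, 11.4%, 5.99% and 2.04%. The strongest of replicate 2 at genes without a promoter peak in replicate 1 were at Usp51 and Phka1 on the X and at Prkd1, Plcb1 and Phpt1 on autosomes. At Phpt1 the window was covered by 39.3% in replicate 1 and 28.0% in replicate 2, so peaks lay near its promoter in both. The 10 kb windows of Usp51, Phka1, Prkd1 and Plcb1 held no peak in replicate 1, and in replicate 2 the coverage was 16.3% at Phka1 and 2.87% at Prkd1.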

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

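The test of how evenly peaks are spread along the X chromosome was chosen after the result had been seen, as was the comparison of the listed replicated peaks with both replicates' own lists. In addition to the protein-coding genes reported on above, 346 long non-coding genes whose promoters lie apart from protein-coding promoters had a promoter peak in the replicated list, or 3.47% of 9976 such genes, and the shares in the replicates' own lists were 7.09% and 3.65%.

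The X chromosome held 14.2% of the peaks of replicate 2 and 7.03% of those of replicate 1, and in both replicates the peaks gathered in the same stretches: the 8 bins of 5 Mb with the most peaks were the same 8 and held 76.2% and 77.9% of the X peaks, with Pearson's r of 0.998 and Spearman's rho of 0.987 across 34 bins, which are not independent. The weak peaks, those with a −log10 q under 2, had an r of 0.993 between the replicates on the X and of 0.787 to 0.970 on the autosomes, so agreement along a chromosome is not particular to the X. GC content, CpG content and gene density, fitted on 1 Mb bins of the autosomes, fell short of the weak peaks on the whole X. These were 4.22 times the prediction in replicate 1 and 10.3 times in replicate 2. In the densest decile of bins the ratios were 9.09 and 28.3. A part of this comes from choosing the densest bins, since that choice gave 1.48 and 1.71 on the autosomes. The relation fitted on the autosomes thus did not account for the weak peaks of the X. An excess over a fit is by construction what the fit leaves over, so it does not by itself exclude these properties as the cause. No whole-chromosome ratio was at hand for single autosomes, so how unusual the values of the X are is not known. In replicate 1 the X had only 1.09-fold the autosomal peaks per megabase. An even gain of X copies in the ChIP libraries over the control stays open, because the clumping of these weak peaks on the X, as the squared coefficient of variation beyond counting noise, was 1.89 against at most 1.49 on an autosome in replicate 1 and 2.07 against 1.95 in replicate 2, and the lower ratio of 1.06 is too close to 1 to decide (with predictions scaled to each chromosome's own total, the densest decile held 2.15 and 2.74 times the prediction on the X and at most 1.94 and 2.40 times on an autosome). A broad mark on the inactive X of the female embryos in the pools is a candidate explanation that was not tested, since the sex make-up of each pool is not given in the sources used here.

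Of the 18905 peaks in the replicated list, 7261 did not overlap a peak in both replicates' own lists, of which 5952 overlapped replicate 1 alone, 919 replicate 2 alone and 390 neither. These peaks were weaker, with a median enrichment value of 3.02 against 3.77 for the others, a difference of 0.750 (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give), and narrower, at 330 bp against 620 bp. A peak that is missed in 1 replicate is bound to be weaker in the pooled call, so this difference does not decide whether they are peaks near the calling limit, and 64.0% of them reached a −log10 q of 2, against 90.5% of the others. The prediction fixed beforehand asked for this difference alone and was met, and the condition that most of them also lie under that q was added to the script after the values had been seen. Peaks on the X were missed more often, at 53.4% against 36.9% on the autosomes, but an excess of X peaks is not the whole cause, since 12.7% of the 7261 lay on the X, and no biological explanation was tested.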

How the results depend on the processing

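Keeping only listed replicated peaks that overlap both replicates, and using only the autosomes for the replicate overlap, were chosen after seeing the data, and the other alternatives before. Of 253 alternative values, 228 kept their direction and their side of the threshold or moved by less than the spread between replicates. The covered share of the X relative to autosomes ran from 0.701 to 1.61 over the replicates' own lists and was 1.45 as peaks per megabase. The median of the 10 widest regions was 42.9 kb with gaps of 1 kb and 97.8 kb with gaps of 10 kb, by construction. Intestinal epithelial differentiation genes fell below other genes with peaks that overlap both replicates, at 9.38% against 12.0%. They also did so without replicate 1, at 12.5% against 13.9% (21.9% without replicate 2). With the 5'-most start alone they were level with other genes, at 12.5% for both. The adjusted Fisher's exact p was 1 in each of these 3. Among CpG-rich promoters alone, 100% of those genes and 100% of blood and immune genes were marked (adjusted p = 0.0457 for both, Fisher's exact), from 2 genes in each list. Adjusted Fisher's exact p-values follow in parentheses. Cell cycle inhibitors passed with the pooled list at 57.1% (0.0281). Imprinted genes, at 26.9%, passed with peaks that overlap both replicates (0.0419), the 5'-most start (0.0484) and 500 bases in the promoter (0.0284). Liver genes, at 0%, passed with the pooled list (0.0287) and the 2.5 kb promoter (0.0477). Housekeeping genes, at 0%, no longer passed with peaks that overlap both replicates (0.0579), 500 bases (0.0891) or CpG-rich promoters (0.0705). Germline genes no longer passed with the pooled list at 3.70% (0.0851), and at 0% with a −log10 q of at least 2 (0.0556), peaks that overlap both replicates (0.0795), the 5'-most start (0.0521), 500 bases (0.0886) or CpG-rich promoters (0.625), and over the replicates' own lists they ran from 0% to 7.41%. Apart from the thresholds and gaps named, the cause was not tested. No paired analysis was possible because there was 1 group. Depth is unknown, so the weaker calls of replicate 2 cannot be set against its depth.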

Other observations

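The grouping of genes by the stem of their symbol and the look at the peaks with the highest −log10 q were chosen after the data had been seen. Promoter peaks were also counted in 355 families of at least 8 genes that share a symbol stem, some of which, such as Olfr, Wnt, Fgf and the Hox clusters, are on the fixed lists too. After Benjamini-Hochberg adjustment of Fisher's exact tests, 41 families carried promoter peaks more often than other genes and 11 less often, and members that lie next to each other are not independent. Voltage-gated calcium channel genes (Cacna) had a promoter peak in 13 of 14 cases (adjusted Fisher's exact p = 9.09e-09; 92.9% ± 10.1 over the replicates, SD, n = 2). Synaptotagmins (Syt), calcium sensors of vesicle release, had one in 14 of 17 (adjusted Fisher's exact p = 3.94e-08; 76.5% ± 16.6), serotonin receptors (Htr) in 11 of 14 (adjusted Fisher's exact p = 2.92e-06; 75.0% ± 5.05) and metabotropic glutamate receptors (Grm) in all 8 (adjusted Fisher's exact p = 3.69e-06; 93.8% ± 8.84). In potassium channel families, 7 of 8 Kcna, 7 of 8 Kcnh, 10 of 14 Kcnk and 9 of 15 Kcnj genes were marked, and 6 of 8 Cacng and 23 of 73 Gpr genes also passed the threshold. Some families of channels and receptors did not pass it, such as sodium channels (Scn) with 6 of 14 and nicotinic receptor subunits (Chrna) with 3 of 9 genes marked, and no class of families was tested as a whole.

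Collagen genes (Col), a main product of mesenchyme, were marked in 22 of 45 cases (adjusted Fisher's exact p = 1.01e-06), at 62.2% in replicate 1 and 35.6% in replicate 2. At the other end, none of 331 vomeronasal receptor genes (Vmn), none of 67 histone genes (Hist) and 20 of 394 zinc finger genes named Zfp, or 5.08%, had a promoter peak, with adjusted Fisher's exact p of 1.44e-20, 8.59e-04 and 2.13e-07. The replicates' own lists marked 7.61% and 4.31% of the Zfp genes.

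Promoter peaks were common at genes named for the gut's own cell types, with 77 of 146 genes in the lists for epithelium, mesenchyme, enteric nervous system and endothelium that are not on the neural list. The CpG class of their promoters alone is not enough to account for this. Among CpG-rich promoters, 80.9% of the 47 gut lineage genes had a peak against 17.9% of other genes (odds ratio 19.4, Fisher's exact p = 1.59e-20, two-sided). CpG content can still differ between promoters within that class, so it is not excluded as a cause. Only 2 of the 32 epithelial differentiation genes were CpG-rich, and 5 of the 32 had a promoter peak. The neural, mesoderm and endoderm organ factors were marked at 88.2% to 100%, so the excess is not shown to be particular to gut lineages. If the mark lay on these promoters in only a part of the cells, their enrichment values would be lower than those of neural factors. The value of a gene was the highest of any peak at any of its promoters, and the number of starts per gene was not matched between sets. The median enrichment value of marked genes in the CpG-rich class was 4.85 in 38 gut lineage genes and 6.57 in 30 neural factors, a difference of 1.72 (permutation p = 3e-05, one-sided). The difference is not specific to gut lineages, and they do not share it alike. Over all marked promoters, whatever their CpG content, the median of 6.44 for neural factors was exceeded only by 6.51 for Hox groups 10 to 13. Outside the gut lists it was 6.12 for factors of foregut, pancreas and other endoderm organs and 5.87 for Wnt ligands. Lower medians were 5.46 for mesoderm factors, 5.17 for Hox groups 1 to 9 and 4.50 for hedgehog, BMP and FGF ligands. Among the gut lists it was 6.30 for secretory and enteroendocrine factors, 5.05 for enteric, 4.45 for endothelial and 3.89 for mesenchyme genes. Epithelial factors had 4.01 and epithelial differentiation genes 3.51. The hypothesis therefore stays open, and a lower value could also come from less of the mark in every cell, which peak lists of whole tissue do not separate.

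The highest −log10 q of the replicated list, 63.2, belonged to a peak of 482 bp on chromosome 5 from 146261002 to 146261483, inside Cdk8 and outside its exons, with an enrichment value of 5.61. The next, 44.2, belonged to a peak on chromosome 17 from 39843070 to 39846777 in the non-coding gene Gm26917, where the enrichment value was only 2.11, against 11.8 for the peak at Wnt3a that followed it with a −log10 q of 42.7. A neighbouring peak on chromosome 17 from 39847986 to 39848895 came after Wnt3a, with a −log10 q of 41.5 and an enrichment value of 2.07. No repeats or regions of artefact signal were filtered out here. A high −log10 q alone therefore does not show that the peaks at Cdk8 and on chromosome 17 are sites of the mark.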
